A study of Oikopleura dioica with 14 samples.

How the data were processed

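Polyadenylated RNA from pools of whole animals of one genotype was sequenced from a kit for single cells and low input, per the labels' protocols. The authors deposited 1 table per stage with estimated counts per gene, 1 column per library, neither scaled to depth nor pooled over replicates. Per the submitters' processing notes kallisto 0.46.0 and DESeq2 were used. The transcript index, the annotation release and any filter are not given in the sources used here. Between 4.37% and 11.3% of the deposited estimated counts per library had any fractional part (4.22% to 10.8% lay more than 0.01 from a whole number), and they were rounded to whole numbers before testing. kallisto divides reads among similar transcripts, so counts of near-identical gene copies are uncertain, and which genes these are was not analysed here.

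The 3 tables list the same 17212 identifiers and were joined by identifier, and 271 identifiers had 0 counts in every library. None of them matched the 17178 genes of the reference table (assembly OKI2018_I68_1.0), so no gene names, coordinates or functions were used and the functional gene lists fixed before the data were examined were not run. Samples were grouped by the genotype and stage in their titles. A wild-type column at 8 hpf carries a number that no titled sample has. It was assigned to its group as an unnumbered replicate. Each library was compared with every other library of its stage. The chi-square per degree of freedom was at least 102 for every pair, so no library was a repeat of another. Total counts ran from 2803712 to 15682947. Stage goes together with depth, since the 4 hpf libraries hold 2803712 to 3941906 counts and all others at least 10350791, and the labels give no sequencing batch. Intervals and floors cover counting error only, because reads amplified without molecular identifiers are not independent molecules.

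Each comparison was fitted with edgeR 4.0.16 in R 4.3.3, using filterByExpr with the groups compared, TMM factors, the quasi-likelihood F test, two-sided, and Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. Each stage was fitted on its own libraries. The comparison over all stages had stage as an additive factor, the interaction was tested over 6 group means, and the wild-type changes used the 6 wild-type libraries. Standard errors of log2 fold changes came from the fitted weights and the moderated quasi-likelihood dispersion. CPM were computed on the total count per library without further factors. Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom (limma 3.58.1), no low-count filter, a mean of at least 5 CPM, a minimum 1.5-fold change, 1 fit of all 14 libraries, a replicate block, and leaving out each library or stage in turn. DESeq2 was given all 17212 identifiers without the expression filter used for edgeR and limma-voom, so its counts differ by gene set as well as by tool. After the data were examined, further alternatives were added. They were a filter of 100 counts in 2 libraries, fits without the run of 43 genes, fits without the 2 mutant libraries with the fewest genes at 100 counts at 6 and 8 hpf, a block on column numbers, stage lists chosen by p, and other choices of low-count genes. The rule for unnamed identifiers, set before the data were examined, allowed 2 that rose and 2 that fell, by smallest adjusted p at 5 CPM or more and with no overlap between groups.

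The run of genes was searched for after the called genes were seen to lie close together in identifier order. Each gene received a score, a Poisson log-likelihood ratio for its counts, capped at 15 per library, being lower in mutants than their wild-type level predicts, and the consecutive stretch with the highest sum was taken. Scores were permuted over the gene order 1000 times. The scan was tested on simulated data and found 49 of 50 planted runs of 40 genes in the 4 hpf libraries and 50 of 50 in those of 6 and 8 hpf. The edgeR step was tested on simulated counts drawn from the real means, dispersions and library sizes with 50 genes changed at each of several fold sizes. At 64-fold it called 23 of 50 genes at 4 hpf, 0 at 6 hpf, 2 at 8 hpf and 0 over all stages. For the wild-type change from 6 to 8 hpf it called 0 of 50 at 64-fold. Regroupings drew 100 splits within stages for the comparison over all stages, the real one included, and used every split of the libraries at each stage. Scans and closing tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9.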

Results

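The libraries compared whole Oikopleura dioica animals mutant for Pax37b (Pax37b-/-) with wild-type animals, to find genes whose expression depends on this gene. Oikopleura dioica is a planktonic tunicate that lives inside a secreted house, and Pax37b belongs to the Pax3/7 family of paired-box transcription factors. The series title ties the gene to the Fol territory, a part of the epithelium that makes the house. Animals came from crosses of heterozygous parents, were genotyped one by one and were pooled by genotype at 4, 6 and 8 hours post fertilization (hpf). The 14 libraries comprised 2 mutant and 2 wild-type pools at 4 hpf, 3 and 2 at 6 hpf, and 3 and 2 at 8 hpf. The labels call them biological replicates but do not say whether each came from its own cross. Total counts per library were 2803712 to 3941906 at 4 hpf, 13038439 to 15465563 at 6 hpf and 10350791 to 15682947 at 8 hpf. The tables list 17212 gene identifiers without names, and none matched the reference gene table, so Pax37b itself was not analysed here and genes are given by identifier.

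Libraries of the same genotype and stage shared few of their abundant genes at the later stages. Of the genes at 100 counts or more in either library of a pair, 46.9% on average were at that level in both libraries of one genotype at 4 hpf, 28.6% at 6 hpf and 19.2% at 8 hpf. Pairs of different genotypes shared 46.3%, 27.4% and 17.8%, close to the values within a genotype. Because the 4 hpf libraries hold fewer counts, 100 counts mark a higher level there. The overlaps were not computed on thinned counts, so the fall between stages may partly reflect depth. The number of genes at 100 counts or more ran from 3316 to 4400 at 4 hpf and from 2168 to 4645 at 6 hpf. At 8 hpf it was 1799, 2390 and 783 in the mutant libraries against 4466 and 2729 in wild type. After all libraries were thinned to 2803712 counts, the number of genes at 20 counts or more still ran from 870 to 4406 at 8 hpf. The spread between libraries was accordingly wide in every fit, with a biological coefficient of variation of 1.31 at 4 hpf, 1.83 at 6 hpf and 1.45 at 8 hpf.

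**Figure D1:**
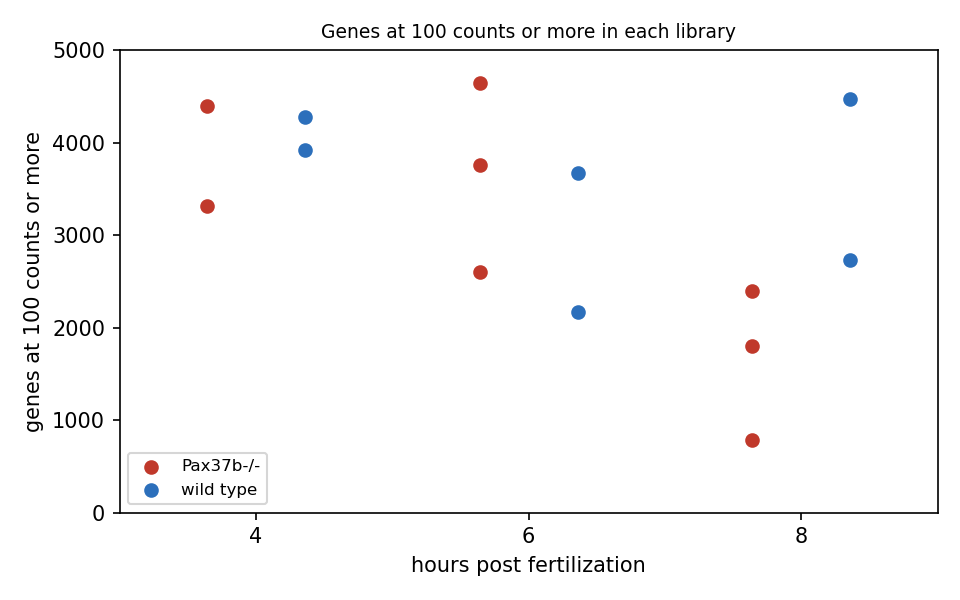
Number of genes at 100 counts or more (vertical axis) in each of the 14 libraries by stage in hours post fertilization, with mutant libraries in red and wild type in blue, 1 point per library. At 8 hpf the mutant libraries sat at 783 to 2390 and the wild-type libraries at 2729 and 4466.

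At 4 hpf the clearest differences were genes that were abundant in wild type and nearly without counts in the mutants (levels in CPM, counts scaled to a common library total). GSOIDG00006051001 stood at 3.20 ± 0.226 CPM in mutants (SD, n = 2) against 3092 ± 1076 CPM in wild type (SD, n = 2), a log2 fold change of -9.65 (SE 0.425, edgeR adjusted p = 0.00209). GSOIDG00006031001 fell as steeply, from 2343 ± 618 CPM in wild type to 2.66 ± 0.526 CPM in mutants, a log2 fold change of -9.52 (SE 0.456, edgeR adjusted p = 0.00209). In the other direction GSOIDG00006297001 rose to 7473 ± 422 CPM from 1295 ± 12.03 CPM (log2 fold change 2.78, SE 0.262, edgeR adjusted p = 0.0246). GSOIDG00003612001 rose to 3289 ± 559 CPM from 324 ± 78.7 CPM (log2 fold change 3.60, SE 0.364, edgeR adjusted p = 0.0403). Of 6933 genes tested with edgeR's quasi-likelihood test, 5 passed the threshold, 2 higher and 3 lower in mutants, and 420 had an unadjusted p under 0.05. Genes with both mutant libraries on one side of both wild-type libraries made up 35.0% of those tested, where chance gives 33.3%. No gene passed in 1 fit of all 14 libraries, which also changed the genes tested to 12850, and DESeq2 called 461. limma-voom called 4 genes, all higher in mutants and 2 of them shared with the 5, and left both fallen genes named above at an adjusted p of 0.438. DESeq2 passed these 2 but left GSOIDG00006297001 at 0.235 and GSOIDG00003612001 at 0.0867. In simulated counts for the same genes, 9 of 50 genes changed 16-fold were called, and 5 unchanged genes were called over all fold sizes together.

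All 3 genes that fell at 4 hpf, both named ones included, belong to a single run of 43 genes with consecutive places in the identifier order, numbers 6011 to 6056. This run was found after the data were examined. In the mutant libraries 3 to 17 of the 43 genes had any count, against 20 to 42 in wild type. The summed level of the run was 2.45 to 720 CPM in the 8 mutant libraries and 2676 to 8414 CPM in the 6 wild-type libraries, with no overlap. The losses had exceptions, as 1 gene of the run had 157, 2158 and 1107 counts in mutant replicate 2 at 4, 6 and 8 hpf, against 1 and 3, 64 and 11, and 136 and 557 in wild type. Another had 10556 counts in mutant replicate 1 at 6 hpf, against 19612 and 6827 in wild type. Outside the run, 55.6% to 93.6% of genes had a count in mutant libraries and 52.2% to 91.2% in wild type. Scans of the 6 hpf libraries alone and of the 8 hpf libraries alone returned the same 43 genes, and the 4 hpf libraries returned 42 of them. In each scan the run scored above the best run of every one of 1000 random gene orders (permutation p = 0.001, the smallest these permutations can give, one-sided). Whether the order of identifiers follows the chromosome was not tested here.

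**Figure D2:**
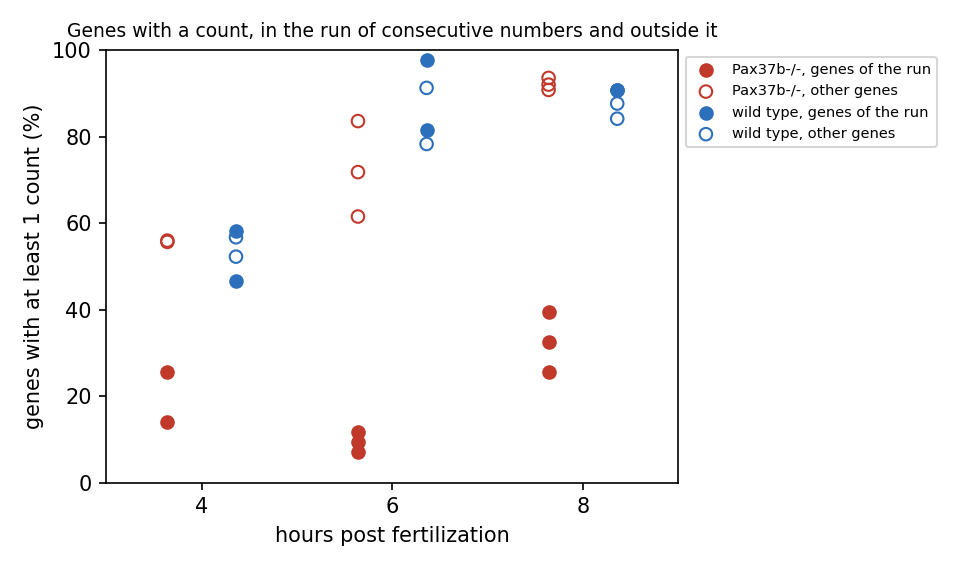
Percent of genes with at least 1 count (vertical axis) by stage in hours post fertilization, for the 43 genes of the run (filled points) and for all other genes (open points), 1 point per library, mutants in red and wild type in blue. Genes of the run had a count in 6.98% to 39.5% of cases in mutant libraries and in 46.5% to 97.7% in wild type.

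At 6 hpf the 4 named genes stayed apart between genotypes, but no gene passed edgeR's test. GSOIDG00006051001 had 0 counts in all 3 mutant libraries against 246 ± 124 CPM in wild type (SD, n = 2), at least 3542-fold lower given a floor of 3 counts over the group (edgeR adjusted p = 0.661). GSOIDG00006031001 likewise had 0 counts in the 3 mutant libraries against 466 ± 471 CPM, at least 6701-fold lower (edgeR adjusted p = 0.661). The floor covers counting error only. GSOIDG00006297001 was at 1831 ± 1060 CPM in mutants (SD, n = 3) and 250 ± 77.2 CPM in wild type (log2 fold change 2.54, SE 2.00, edgeR adjusted p = 0.67). GSOIDG00003612001 was at 732 ± 615 CPM against 20.5 ± 22.1 CPM (log2 fold change 4.97, SE 2.80, edgeR adjusted p = 0.661). For these 4 genes each of the 3 mutant libraries lay on the same side of both wild-type libraries as at 4 hpf. Of 6685 genes tested with edgeR, 0 passed and 341 had an unadjusted p under 0.05. Of the same 6685 limma-voom called 153, while DESeq2, given all 17212 identifiers, called 2199. limma-voom passed GSOIDG00006051001 (adjusted p = 3.74e-08) and GSOIDG00006031001 (3.6e-11) but not the other 2 (0.785 and 0.808), and DESeq2 passed all 4 (1.42e-05, 1.85e-06, 0.00609 and 0.00437). In simulated counts for this comparison, edgeR called 0 of 50 genes changed 64-fold, and the other tools were not simulated.

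**Figure D3:**
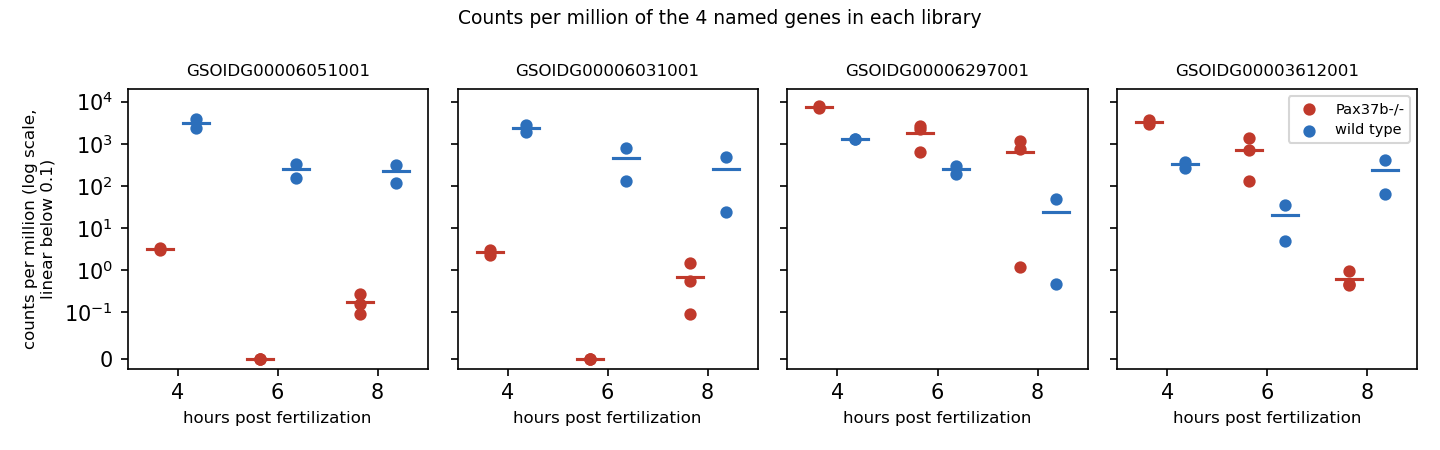
CPM (vertical axis, logarithmic, linear below 0.1) of the 4 named genes in each library by stage in hours post fertilization, with points for libraries and bars for group means, mutants in red and wild type in blue. GSOIDG00006051001 and GSOIDG00006031001 lay lower in every mutant library at every stage, whereas GSOIDG00003612001 lay higher in every mutant library at 4 and 6 hpf and lower in every one at 8 hpf.

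At 8 hpf the 2 named genes of the run again had few counts in mutants. GSOIDG00006051001 was at 0.175 ± 0.0902 CPM in mutants (SD, n = 3) and 221 ± 143 CPM in wild type (SD, n = 2), a log2 fold change of -11.29 (SE 2.59, edgeR adjusted p = 0.166). GSOIDG00006031001 was at 0.700 ± 0.695 CPM against 253 ± 324 CPM (log2 fold change -9.05, SE 2.65, edgeR adjusted p = 0.166). GSOIDG00003612001, higher in mutants at the earlier stages, was now at 0.630 ± 0.291 CPM in mutants and 236 ± 241 CPM in wild type (log2 fold change -9.75, SE 2.56, edgeR adjusted p = 0.166). GSOIDG00006297001 was at 632 ± 583 CPM against 24.6 ± 34.1 CPM (log2 fold change 4.33, SE 2.95, edgeR adjusted p = 0.407), with 2 of 3 mutant libraries above both wild-type libraries and the third, at 1.19 CPM, below the higher of them. Of 8704 genes tested with edgeR 0 passed, although 2611 had an unadjusted p under 0.05, and limma-voom also called 0. The count depended on the scaling and tool, with 26 calls under RLE size factors, 2521 under upper-quartile factors (2500 higher in mutants) and 3806 under DESeq2 (3395 lower in mutants), which passed 3 of the 4 named genes but not GSOIDG00006297001 (0.139). Without the unnumbered wild-type library edgeR called 2466 genes, 387 higher and 2079 lower, the lone wild-type library being assumed to vary like the mutant group.

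Genes with low counts leaned to opposite sides at different stages. Of 2945 tested genes that stayed under 100 counts in every 8 hpf library, 2159 (73.3%) had a higher CPM in each mutant library than in either wild-type library and 20 had a lower one, where chance gives 10% each way. Without the expression filter 52.4% of 9725 such genes lay higher and 1.07% lower. Scaled CPM kept this direction, with 43.4% higher under TMM, 45.6% under RLE and 97.0% under upper-quartile factors. At the earlier stages the same cut gave other sets of tested genes, and these leaned the other way. Of 678 at 6 hpf, 1.77% lay higher and 20.1% lower. Of 1036 at 4 hpf, 8.98% lay higher and 26.3% lower, where chance gives 16.7%. The lean at 4 hpf was not particular to low-count genes, since 13.7% of genes that reached 100 counts there lay higher and 21.2% lower. Scaled and unfiltered versions were computed for 8 hpf only. Of the 5759 8 hpf genes that reached 100 counts, 776 lay higher and 918 lower in every mutant library. A closely related measure divided the 8 hpf libraries the same way, with 74.6% to 81.9% of identifiers at 1 to 30 counts in mutants against 58.6% and 66.3% in wild type, and 6.58% to 9.38% without a count against 12.4% and 15.9%. All genes under 100 counts at 8 hpf took 0.499% to 0.879% of the counts in the mutant libraries and 0.246% to 0.354% in wild type. At 6 hpf this share overlapped between genotypes, with 0.0927% to 0.267% in mutants and 0.189% and 0.379% in wild type. At 4 hpf it was 0.999% and 1.56% in mutants and 1.87% and 2.33% in wild type.

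Over all stages, with stage as a factor, 23 of 12850 genes differed between the 8 mutant and 6 wild-type libraries, 4 higher and 19 lower in mutants. Of the 19, 10 belonged to the run described above, of which 26 genes could be tested. GSOIDG00006051001 averaged 0.867 ± 1.45 CPM in mutants (SD, n = 8) and 1187 ± 1555 CPM in wild type (SD, n = 6), a log2 fold change of -11.41 (SE 1.52, edgeR adjusted p = 0.031). GSOIDG00006031001 averaged 0.926 ± 1.19 CPM against 1020 ± 1095 CPM (log2 fold change -10.88, SE 1.54, edgeR adjusted p = 0.0342). Both were lower in 8 of 8 mutant libraries than in any wild-type library of the same stage, yet the first passed in 11 of 27 alternatives (6 of the 14 that left out 1 library) and the second in 6 of 27 (2 of 14). In all, 3 genes were called both here and at 4 hpf, and 1146 genes had an unadjusted p under 0.05. The smallest adjusted p of the comparison was 0.031, and 0 genes passed without the 43 genes of the run, without the 6 hpf stage or without the 8 hpf stage. Without the 4 hpf stage 23 genes passed, 10 of them among the 23 of the full comparison.

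The genotype effect was then compared between stages. No gene passed the interaction test over 12850 genes (edgeR, smallest adjusted p = 0.173), with 2934 genes at an unadjusted p under 0.05 and 1085 called by DESeq2. GSOIDG00003612001 gave the mutant minus wild-type log2 fold change that differed most among the named genes, lower at 8 than at 4 hpf by a log2 difference of -13.08 (SE 3.17, edgeR adjusted p = 0.222) and lower at 8 than at 6 hpf by -14.47 (SE 3.02, edgeR adjusted p = 0.148). For GSOIDG00006297001 the 8 minus 4 hpf difference was 1.43 (SE 2.99, edgeR adjusted p = 0.958).

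Wild-type development gave few calls as well. From 4 to 6 hpf 2 of 9334 genes rose and 0 fell, and from 6 to 8 hpf 1 rose and 1 fell (edgeR, 2 libraries per stage). Unadjusted p values under 0.05 numbered 1746 and 1511, and DESeq2 called 2716 and 4150 genes. In simulated counts for the 6 to 8 hpf change, edgeR called 0 of 50 genes changed 64-fold. The few calls there do not show that few genes changed. The 4 to 6 hpf change was not simulated. The stage lists that were to be tested in the mutants, genes changing between the 2 other stages in a fit of those 4 wild-type libraries alone, held 2 rising genes and 1 falling gene for 4 hpf and 0 genes for 6 and 8 hpf, so they were not tested. The fits behind these lists were not simulated, so short or empty lists do not show a lack of change.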

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

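The splits of the libraries over all stages, the interaction test and the edgeR and DESeq2 fits were planned before the data were examined. The other tests in this part were chosen after the results were seen.

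GSOIDG00003612001 stood out because its mutant libraries lay on opposite sides of wild type at different stages, above both wild-type libraries in 2 of 2 mutant libraries at 4 hpf and 3 of 3 at 6 hpf, and below both in 3 of 3 at 8 hpf. The difference of its log2 fold changes was -13.08 between 8 and 4 hpf and -14.47 between 8 and 6 hpf, and neither passed the interaction test (edgeR adjusted p = 0.222 and 0.148). Of 4747 genes tested at 4 and 8 hpf, 84 (1.77%) switched in this direction, where chance gives 1.67%, and 259 (5.46%) in the opposite one.

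The run of 43 genes nearly without counts in mutants does not come from a chance gene order, since none of 1000 random orders reached its score (permutation p = 0.001, the smallest these can give). A lower yield of the mutant libraries is also argued against, because for the 42 of these genes that the 4 hpf libraries alone define, 0 of 17088 other runs as long were as empty in any mutant library at 6 and 8 hpf. A candidate explanation is that part of the wild-type sequence is missing from the chromosome that carries the mutation. It could be a deletion or a sex-linked or divergent stretch inherited with the mutation. However, 3 genes of the run exceeded 30 counts in a mutant library, and 2 of them reached 100. The third, GSOIDG00006043001, had 34 in mutant 4 hpf replicate 1 against 0 in both wild-type libraries of that stage. Of the 42 genes, 14 stayed under 100 counts in all libraries. Pooled, they had 17 counts in mutants at 6 and 8 hpf where 429 were expected from other such genes. The ratio was 0.0396 (95% Poisson interval 0.0231 to 0.0634), the lowest in other runs being 0.215. All 17 counts came from GSOIDG00006043001, which had up to 23 counts in a wild-type library at these stages. The rest of the 14 had no count in these mutant libraries, but GSOIDG00006016001 had none in wild type either. Lower transcription of genes that are present cannot be told apart from missing sequence, even with an upper bound of 0.0634 on the pooled ratio. The reason is that whether the low counts come from DNA or from transcripts is not known. A dependence of the run's genes on Pax37b stays open and untested.

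At 8 hpf 73.3% of low-count genes lay higher in every mutant library. Genes of 1 library can move together, so they are not independent trials. Of the 10 splits of the 5 libraries into 3 and 2, the real one gave the highest share, the next being 12.7%. With so few splits the real one cannot reach a share under 0.05. Lower depth is argued against as the whole cause, because after thinning to 10350789 counts per library the share was still 66.2%. The genes were chosen by raw counts before thinning, so an effect of depth on that choice was not removed. Chosen by a mean under 1, 2 or 5 CPM without the filter or thinning, 49.8% to 51.5% lay higher. Whether these genes change with genotype at 8 hpf cannot be told from 5 libraries, and values at 6 hpf do not decide it. Of all 5283 genes tested at both stages, whether low in counts or not, 5.47% lay on opposite sides and 2.61% on the same side (chance gives 2% each). Of the 2159 genes higher at 8 hpf, 1.71% lay higher and 22.4% lower in every mutant library at 6 hpf.

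DESeq2 called 2199 genes at 6 hpf where edgeR called 0. Of the 10 splits of the 5 libraries into 3 and 2, 8 gave at least 2199 DESeq2 calls, the real split included. The highest count outside the real split was 2740. The real count lay below the median of the other splits, 2296, so the number of DESeq2 calls does not set the genotypes apart. A share under 0.05 cannot be reached with 10 splits. edgeR called 0 genes in all 10. Whether the DESeq2 calls come from the tool, from its larger set of genes or from a structure of the samples was not tested. At 4 hpf DESeq2 called 461 genes in the real split and 436 and 333 in the 2 others, where edgeR called 5, 0 and 0. At 8 hpf DESeq2 called 3806 genes in the real split and at most 3177 in another, while edgeR called 0 in the real split and up to 16 in others.

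Over all stages edgeR called 23 genes. Only 1 of 100 drawn splits within stages, the real one, gave as many, the highest of the others giving 1. This argues against chance for that count, as far as 100 splits can tell. As 0 genes passed without the run of 43 genes, the splits do not speak for the called genes outside it.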

How the results depend on the processing

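The alternatives that leave out the run, require 100 counts in 2 libraries, drop the 2 mutant libraries, use column numbers for the block or choose low-count genes in other ways were chosen after the data were examined. At each stage, and over all stages for the 2 that fell, the named genes kept their direction in every alternative in which they were fitted, but the counts of called genes moved. The cause was not tested unless stated.

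At 4 hpf the 5 calls became 3 with upper-quartile factors, 461 with DESeq2 (202 higher and 259 lower), 30 without a filter, 14 at 5 CPM, 0 in the fit of all 14 libraries, 2 at 100 counts in 2 libraries and 0 without the run. limma-voom called 4, all higher. Leaving out 1 library gave 13 and 21 (mutant replicates 1 and 2) and 17 and 8 (wild-type replicates 1 and 2), a range of 8 to 21, the lone library being assumed to vary like the other group. GSOIDG00006051001 and GSOIDG00006031001 passed in 12 of 14 alternatives, GSOIDG00006297001 in 10 of 15 and GSOIDG00003612001 in 9 of 15. At 6 hpf 0 calls became 153 with limma-voom and 2199 with DESeq2. At 8 hpf 0 calls became 26 with RLE factors (20 higher), 2521 with upper-quartile factors (2500 higher) and 3806 with DESeq2 (411 higher). The upper-quartile factors there ran from 0.22 to 10.4 and moved the median log2 fold change of all genes by 4.48, against 0.29 for RLE. Upper-quartile shifts were -0.48 at 6 hpf and -0.13 at 4 hpf. Leaving out mutant replicates 1, 2 and 3 at 8 hpf gave 29, 7 and 13 calls, wild-type replicate 1 gave 0 and the unnumbered wild-type library 2466. The 73.3% of low-count genes higher in every mutant library at 8 hpf became 52.4% without the filter, 43.3% for genes that fail it, 49.8% to 51.5% for all under 1, 2 or 5 CPM on average, 74.1% to 85.6% without a mutant library (chance gives 16.7%) and 79.4% and 86.4% without a wild-type library (25%).

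Over all stages the 23 calls became 11 with RLE factors, 0 with upper-quartile factors, 1341 with DESeq2 (261 higher), 6 with limma-voom, 42 without a filter, 0 at 5 CPM, 14 with a minimum 1.5-fold change, 0 at 100 counts in 2 libraries, 0 without the run, 0 without the 6 or the 8 hpf stage and 0 without the 2 mutant libraries. Leaving out 1 library gave 0 to 29 calls. The count was 29 without wild-type 4 hpf replicate 1, 9 without wild-type 4 hpf replicate 2, 5 without wild-type 6 hpf replicate 2, 3 without mutant 4 hpf replicate 2 or mutant 8 hpf replicate 3, 1 without wild-type 8 hpf replicate 1, and 0 without any of the other 8. For the interaction 0 calls became 1085 with DESeq2 and stayed 0 in the other 20 alternatives. Wild-type calls from 4 to 6 hpf, 2 at first, became 12 with RLE factors, 2716 with DESeq2, 4 without a filter, 5 at 100 counts in 2 libraries and 0 to 12 with 1 library left out. From 6 to 8 hpf 2 calls became 4150 with DESeq2 and 0 to 12 with 1 library left out.

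The labels tie no number to a cross, so pairing is unknown. Same-numbered libraries' deviations from group means correlated by -0.013 at 4 hpf, -0.041 and -0.029 at 6 hpf, and 0.006 and -0.003 at 8 hpf. With so few libraries this excludes no pairing. A replicate block gave 19 calls at 4 hpf and 0 at 6 hpf. The planned block by label number was not run at 8 hpf, over all stages, for the interaction or in wild type, since 1 wild-type column has none. A replicate block on column numbers gave 19 calls at 8 hpf, 0 over all stages, 0 for the interaction, and 4 and 1 for the wild-type changes. Set tests of stage and functional lists were not run, for want of members and of gene names.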

Other observations

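Lists of the 200 wild-type genes with the smallest p in each direction between the 2 other stages, a rule chosen after the planned lists came out with 0 to 2 genes each, gave no call in mutants. The smallest adjusted p over the 6 lists was 0.311 (camera), for genes rising from 4 to 8 hpf tested at 6 hpf, whose median log2 fold change was 2.04. It was 0.922 with an estimated correlation and ran from 0.0502 to 0.922 over 19 alternatives, lowest without mutant 6 hpf replicate 1.

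The opposite scan, for consecutive genes with counts in mutants and none in wild type at 6 and 8 hpf, returned only 2 genes, numbers 13425 and 13426, with a score of 73.9 against 1113 for the run absent from mutants (permutation p = 0.004, one-sided). Single stages did not agree on it. The 8 hpf libraries alone returned the same 2 genes (permutation p = 0.05), the 6 hpf libraries numbers 6714 to 6717 (permutation p = 0.04) and the 4 hpf libraries numbers 7667 to 7670 (permutation p = 0.7).

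Between 41.9% and 75.6% of all identifiers had 1 to 30 counts at 6 hpf and between 58.6% and 81.9% at 8 hpf. At 4 hpf, where libraries hold fewer counts and this range marks other levels, 20.8% to 32.1% did. The 50 most abundant genes took 10.3% to 33.8% of the counts of a library, the highest share in mutant replicate 3 at 8 hpf.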
